A study of Mus musculus with 8 samples.

How the data were processed

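Whole kidneys of mouse embryos at embryonic day 14.5 were compared between wild type and a conditional Mdm4 mutant in which Cre is expressed from a Hoxb7 transgene. Per the labels, total RNA was isolated with a column kit, turned into Cy3- or Cy5-labelled cRNA with Agilent's low-input protocol and hybridised as 4 pairs of 1 wild-type and 1 mutant RNA, each pair on 2 arrays with the dyes exchanged. The labels do not say whether an RNA came from 1 embryo or from several, or what a pair number stands for beyond the shared arrays. The p-values then measure the spread between these 4 pairs, which may be partly technical.

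The scanner files hold the median intensity of each spot and of its local background in both channels, with Agilent's processed signals and flags, all deposited as the scanner software wrote them. The deposited series table holds log10 ratios of Cy5 over Cy3, per the file headers and per a comparison with the scanner files, from which it differed by at most 0.005 after rounding. The table was not turned for the dye swap, and the median of each of its columns was 0. In the scanner files the deposited log10 ratio equalled the ratio of the processed signals for 76.7% to 82.4% of the spots and was 0 for 17.6% to 23.3%. The submitters' processing notes name Agilent Feature Extraction 8.5.1.1, whereas the file headers name 10.7.3.1. The array format named in the labels is smaller than the 62976 spots per array in the files. All 8 arrays lay on 1 slide, so that no slide could be tested as a batch, and dye orientation went together with the position on the slide.

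Intensities were processed with limma 3.58.1 in R 4.3.3. The design written before the data were examined assumed mean spot signals. The files used here gave median signals, which took their place in an otherwise unchanged plan. Background was corrected with normexp and an offset of 50, and each array was normalised by loess with control spots and outlier spots at weight 0. Control spots (3671 per array) and outlier spots (95 to 156 per array) were then left out. Every ratio was turned to mutant over wild type, spots of 1 probe were averaged, and the 2 arrays of a pair were averaged into 1 value, which gives n = 4 pairs. A probe was kept when it was well above background in at least 6 of the 8 channels of a genotype, which left 34594 of 56605 probes. Probes were named through their RefSeq accession in a table of the GRCm38.p6 annotation. That gave 32994 probes a name (58.3%), left 23611 unnamed, and put 22911 genes on the array. No coordinates are printed, because the array design refers to another build. Each of the 16013 genes tested was represented by its brightest kept probe. For 5916 of them more than 1 probe was kept.

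The ratios were tested with lmFit and eBayes against 0, two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Errors are standard errors from this fit unless stated. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation and with fry. The 26 lists covered p53 targets, ureteric bud tip, ureteric trunk and collecting duct, nephron progenitors, early nephron, podocytes, proximal tubule, loop of Henle and distal tubule, renal stroma, endothelium, red blood cells, macrophages and other leukocytes, smooth muscle, neurons, adrenal cortex, gonad, liver, S phase, mitosis, intrinsic apoptosis, hypoxia and glycolysis, immediate early genes, interferon response, renin-angiotensin and kinin genes, heat shock, and signalling and matrix genes of branching. A further list of sex-linked transcripts was described and not tested. In all, 541 list genes were measured, and 6 stood in more than 1 list.

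The lists, the tests, the settings and the rule for naming genes were fixed before the data were examined. The rule named Mdm4, Trp53 and Mdm2, up to 4 measured genes of each list with the smallest p, and 12 genes per direction. Symbols that are accessions, clone names or predicted-gene names (such as those ending in Rik) were left out of those 12. They were to be the largest changes among genes past the threshold with the same sign on all 8 arrays, or, with fewer than 10 such genes, the 12 with the smallest p in each direction, given as values only. The latter applied, and the sign on all 8 arrays was kept as a condition. Genes chosen outside the rule are marked in the text as chosen after their values were seen. Some genes that the rule named are not reported here.

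The steps were tested on simulated data with 16013 genes and the spread of these pairs. At an adjusted p of 0.05, limma recovered 42 of 80 genes changed by 0.50 on the log2 scale, 65 of 69 changed by 1.00 and 51 of 51 changed by 2.00, with 6 false calls. All these changes were put into 1 simulated set. The adjusted threshold is easier to pass where many genes change, so these shares may overstate recovery where few genes do. In simulated sets with independent genes, camera called a list shifted by 0.30 in 10 of 10 sets and 1 of 250 lists that were not shifted. Genes of a real list are correlated, which that simulation leaves out.

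Alternatives changed 1 choice at a time, with the exceptions given after their list. They were another offset, no background correction, Agilent's processed signals, median centring in place of loess, scaling between arrays, the deposited series table, no filter or a stricter filter on dim probes, the median of a gene's probes, tests of probes, robust eBayes with a trend, all 8 arrays in 1 fit with a dye coefficient and the pair as a random block, arrays of 1 dye orientation, separate channels with and without the replicate block, each pair left out, an adjusted p of 0.10, and a fold minimum of 1.5. Of these, the fit of all 8 arrays changed both the unit and the model. Agilent's processed signals and the deposited table took the place of both the background correction and the loess step. The setting without background correction also left out the offset, and robust eBayes and the trend were switched on together. Separate channels were also normalised between arrays. A centring on the tested genes and a sex covariate were added after the data had been seen.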

Results

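Gene expression was measured in whole mouse kidneys at embryonic day 14.5 on 8 2-colour Agilent arrays. The mutant kidneys carried a Hoxb7-Cre transgene, active in the ureteric bud and the collecting duct epithelium that grows from it, to remove Mdm4, an inhibitor of p53. There were 4 wild-type and 4 mutant RNAs in 4 pairs, with 2 dye-swapped arrays of the same RNAs per pair, so that n = 4 pairs. Each array held 62976 spots, of which 60.7% to 70.2% were well above background in a channel, and 0 spots were saturated. The number of arrays limits the precision, and the median standard error over the 16013 genes tested was 0.07 on the log2 scale. All values below are log2 ratios of mutant over wild type unless stated.

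Mdm4 itself was measured by 4 probes, whose mean log2 ratios were -0.18, -0.14, -0.11 and -0.098. Its brightest probe gave -0.03, -0.06, -0.28 and -0.35 in pairs 1 to 4 (mean -0.18 ± 0.07, SE, n = 4). It did not pass limma's test (adjusted p = 0.471), and its ratio differed between the dye orientations, with -0.36 on the arrays with mutant RNA in Cy3 and -0.00062 on those with it in Cy5. The position of these probes relative to the deleted part is not given in the sources used here, and most kidney cells lie outside the Cre-expressing lineage, so these values do not check the labels. Trp53, which encodes p53, had a mean of -0.22 ± 0.07 (limma adjusted p = 0.426), with -1.07 on arrays with mutant RNA in Cy5 and 0.62 on arrays with it in Cy3. Mdm2, a p53 target that encodes a ubiquitin ligase for p53, was at 0.03 ± 0.07 on its brightest probe and at -0.12 on its other probe, and the sign of the former turned in the alternative with the median of its probes, on Cy3-mutant arrays alone, and without pair 4.

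The comparison of mutant with wild-type kidneys asks which transcripts differ when Mdm4 is removed from the ureteric lineage. The mean of a list of transcripts known to be activated by p53 was higher in the mutant in all 4 pairs. Of its 50 measured genes 23 were higher in every pair, among them Gdf15 at 2.34-fold, Eda2r at 2.21-fold and Ccng1 at 2.06-fold. The mean of the ureteric bud tip list was lower in 4 of 4 pairs, with 8 of its 16 genes lower in every pair. That of the ureteric trunk and collecting duct list was lower in 3 of 4. Lists of renal stroma, macrophages and podocytes were higher in 4 of 4 pairs and interferon-stimulated genes in 3 of 4. These are shifts of gene lists, whose calls by camera did not hold with an estimated correlation, and no single gene passed the threshold.

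At an adjusted p of 0.05, limma called 0 of 16013 genes, and the smallest adjusted p was 0.0750. At an unadjusted p under 0.05 there were 1699 genes, 1123 higher and 576 lower, where chance gives 801 on average. With mutant and wild type exchanged in some of the pairs, this count ran from 190 to 1107. The sign was the same in all 4 pairs for 1935 genes higher and 1255 genes lower, together 19.9% of the genes, where chance gives 12.5% on average. Genes are correlated, so both counts can lie far from these averages by chance. Over 2-fold, 22 genes were higher and 5 lower, of which 11 and 1 had the same sign on all 8 arrays. The 22 include the Y-linked genes Eif2s3y, Kdm5d and Ddx3y, and genes such as Ccl20 that were far higher in pair 4 alone. With median centring in place of loess limma called 42 genes, all higher, and with all 8 arrays in 1 fit, a dye coefficient and the pair as a random block it called 39, of which 38 were higher. Median centring moved the median of all genes from 0.01 to 0.14, and with each pair centred on the tested genes, an alternative added after the data had been seen, the count was again 0.

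Of the 50 p53 targets measured, 40 were higher in the mutant. The list mean was 0.30, with 0.37, 0.22, 0.22 and 0.41 in pairs 1 to 4 (camera adjusted p = 2.59e-10). With an estimated correlation the adjusted p of camera was 0.553, and with fry it was 0.153, or 0.0328 in fry's test of changes in either direction. Adjusted over the list alone, 18 targets rose and 0 fell, against 0 adjusted over all genes. The p53-inducible receptor gene Eda2r was at 1.15 ± 0.10, the secreted stress cytokine Gdf15 at 1.23 ± 0.13, Ccng1, which encodes cyclin G1, at 1.04 ± 0.11 and Zfp365 at 0.75 ± 0.06, each higher on 8 of 8 arrays (limma adjusted p from 0.114 to 0.121). Among targets chosen after their values were seen, the desmosome-associated apoptosis gene Perp was at 1.55 ± 0.21, Dglucy at 1.30 ± 0.20, Pmaip1, which encodes the pro-apoptotic protein Noxa, at 1.22 ± 0.15, and the cell cycle inhibitor Cdkn1a at 0.95 ± 0.14, each again higher on 8 of 8 arrays. The pro-apoptotic genes Bbc3 and Bax, also chosen after their values were seen, were at 0.19 ± 0.08 and -0.20 ± 0.11 and did not pass over the list alone. Bbc3 was at 0.39 in pair 1 and -0.01 in pair 4, and Bax at 0.11 and -0.58. Bax had opposite signs in the dye orientations. The mean of the list was above 0 in pair 3 too, where the sex-linked transcripts differed in the opposite direction from the other pairs.

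**Figure D1:**
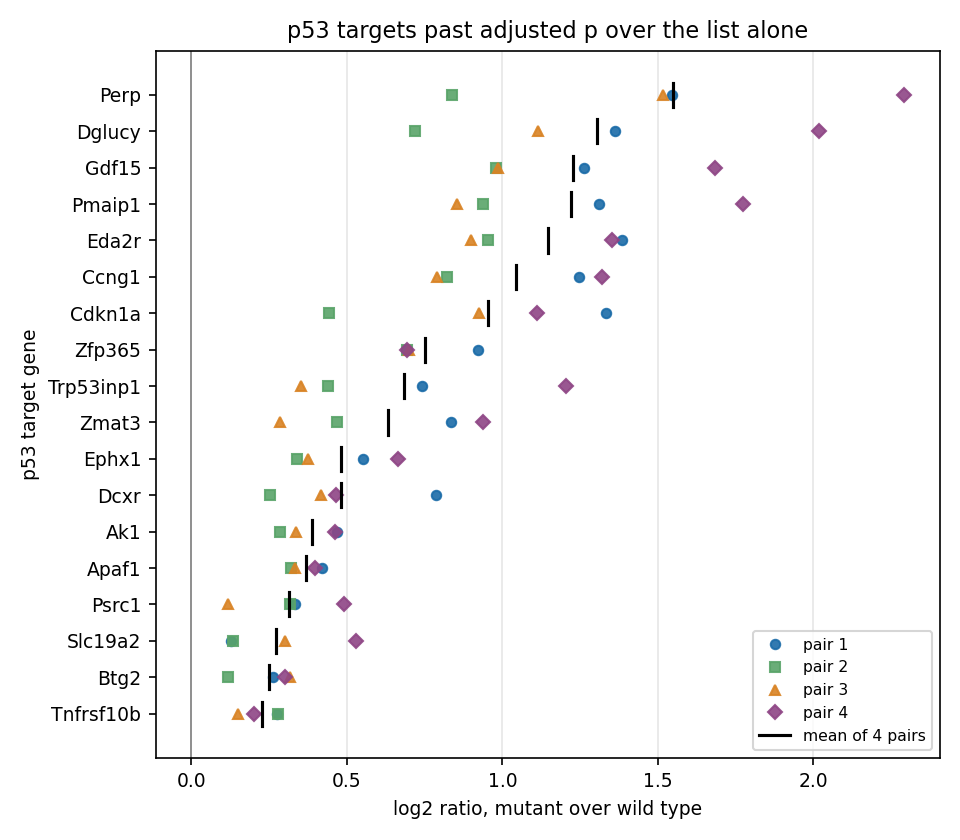
Log2 ratio of mutant over wild type (horizontal axis) of the 18 p53 targets that passed an adjusted p of 0.05 over the list alone (vertical axis), with 1 symbol per pair and a bar at the mean of the 4 pairs. Every symbol lies above 0, and Perp has the highest mean, 1.55.

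As no single gene passed, the genes with the smallest p in each direction and the same sign on all 8 arrays are given as values, without clone and predicted-gene names. Rbm45, which encodes an RNA-binding protein, had the smallest p (0.77 ± 0.05, limma adjusted p = 0.0750), with 0.78, 0.75, 0.75 and 0.82 in pairs 1 to 4. The other higher genes that the rule named outside the p53 list had limma adjusted p from 0.114 to 0.208. They were the phospholipase gene Plcd4 at 1.86 ± 0.20, well above background in 7 of 8 wild-type channels, Pappa2, whose product cleaves binding proteins of insulin-like growth factor, at 0.90 ± 0.11, Plcxd3 at 0.82 ± 0.10, the transcription factor gene Sp6 at 0.69 ± 0.07, the opioid precursor gene Pdyn at 0.61 ± 0.07, Pqlc3 at 0.56 ± 0.06, and Tnc, which encodes the matrix protein tenascin C, at 0.46 ± 0.06. The lower genes had limma adjusted p from 0.297 to 0.366. The homeobox gene Hoxd4 was at -0.70 ± 0.13, Gadd45gip1 at -0.56 ± 0.12, the somatostatin receptor gene Sstr3 at -0.45 ± 0.09 and Npw, which encodes neuropeptide W, at -0.39 ± 0.08. For Hoxd4 the 2 arrays of a pair disagreed in pair 1 (-0.23 with mutant RNA in Cy5, -1.55 in Cy3) and in pair 2 (-1.95 and -0.21). In pairs 3 and 4 Hoxd4 was at -0.41 and -0.43. Sinhcaf (-0.38 ± 0.08), Hap1 (-0.36 ± 0.07), Mfsd13a (-0.33 ± 0.08), the sterol transporter gene Abcg5 (-0.33 ± 0.06), the spectrin gene Sptan1 (-0.32 ± 0.06), the sialyltransferase gene St6galnac2 (-0.32 ± 0.05) and Gcdh, an enzyme gene of lysine breakdown (-0.24 ± 0.05), were lower too.

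Of 16 genes of the ureteric bud tip, 13 were lower in the mutant. The list mean was -0.27, with -0.53, -0.07, -0.05 and -0.44 in pairs 1 to 4 (camera adjusted p = 8.37e-06, but adjusted p = 0.553 with an estimated correlation and 0.399 with fry). In pairs 2 and 3 it was at -0.18 and -0.15 on the arrays with mutant RNA in Cy5 but at 0.04 and 0.05 on those with it in Cy3. Adjusted over the list alone 5 tip genes fell, against 0 over all genes, among them Tmem59l at -0.57 ± 0.15, Gfra1, the co-receptor for GDNF, at -0.52 ± 0.12, and the transcription factor gene Sox8 at -0.40 ± 0.09. Lhx1 (-0.26 ± 0.08), which the early nephron list holds too, was another. Ret, which encodes the GDNF receptor and was chosen after its values were seen, varied between pairs (-1.35, 1.09, -0.42 and -0.57, mean -0.31 ± 0.36). Also chosen after their values were seen, Etv4, a transcription factor gene downstream of Ret signalling, was at -0.57 ± 0.19 and Wnt11, a growth factor gene of the tip, at -0.36 ± 0.13. Both were lowest in pair 4, at -1.22 and -0.83, and closest to 0 in pair 3, at -0.03 and -0.06. Neither passed over the list alone.

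Of 31 genes of the ureteric trunk and collecting duct, 29 were lower, with a list mean of -0.26 (camera adjusted p = 2.18e-08, but adjusted p = 0.564 with an estimated correlation and 0.422 with fry) and 0 past the threshold adjusted over the list alone or over all genes. The list mean was -0.56, -0.32 and -0.36 in pairs 1, 2 and 4 but 0.21 in pair 3, the pair whose sex-linked transcripts differed the other way. Without pair 3 it was -0.41, without pair 1 it was -0.16, and with the sex difference as a covariate, added after the data had been seen, it was -0.11. The keratin genes Krt23, Krt8 and Krt18 were at -0.70 ± 0.17, -0.42 ± 0.12 and -0.42 ± 0.13, and Wnt9b, a signal from the ureteric bud to the nephron progenitors, at -0.60 ± 0.15. Krt8 and Krt18 were at 0.03 and 0.07 in pair 3. With that covariate the tip list was at -0.17, and with median centring the tip and trunk lists were at -0.13 and -0.14, where the median of all genes was 0.14.

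The renal stroma list had a mean of 0.24, with 24 of 27 genes higher and 0.31, 0.20, 0.12 and 0.34 in pairs 1 to 4 (camera adjusted p = 9.78e-09, but adjusted p = 0.553 with an estimated correlation and 0.153 with fry, or 0.0328 in fry's test of changes in either direction). Adjusted over the list alone 8 stroma genes rose, against 0 over all genes, among them the collagen gene Col3a1 at 0.36 ± 0.05, Lum, which encodes the matrix protein lumican, at 0.67 ± 0.10, the Wnt modulator gene Dkk2 at 0.48 ± 0.09, and Tbx18, a transcription factor gene of ureteric mesenchyme, at 0.57 ± 0.11. The macrophage and leukocyte list had a mean of 0.32, with 21 of 21 genes higher (camera adjusted p = 1.62e-06, but adjusted p = 0.553 with an estimated correlation). Its mean was 0.68 in pair 4 and 0.03 in pair 2, and 0.21 without pair 4. Ccl3, a chemokine gene, rose when adjusted over the list alone (0.46 ± 0.09, well above background in 4 of 8 wild-type channels). Tyrobp, an immune receptor adaptor gene, was at 0.34 ± 0.09, Cx3cr1, a chemokine receptor gene, at 0.36 ± 0.12 and Aif1 at 0.27 ± 0.08.

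The podocyte list had a mean of 0.23, with 14 of 16 genes higher (camera adjusted p = 0.000147, but adjusted p = 0.553 with an estimated correlation). Synpo, which encodes synaptopodin, rose when adjusted over the list alone (0.34 ± 0.06), and Nphs1, which encodes nephrin, and Ptpro were at 0.37 ± 0.12 and 0.44 ± 0.14. On the arrays with mutant RNA in Cy3 alone the podocyte list was at 0.17 and was not called. The interferon list had a mean of 0.18, with 18 of 19 genes higher (camera adjusted p = 4.40e-05, but adjusted p = 0.564 with an estimated correlation). It was at -0.02 in pair 1 and 0.41 in pair 3, and at 0.11 without pair 3. Ifi44 rose when adjusted over the list alone (0.41 ± 0.08, well above background in 7 of 8 wild-type channels), and the transcription factor gene Irf7, Rtp4 and Oasl2 were at 0.39 ± 0.11, 0.47 ± 0.15 and 0.19 ± 0.06.

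**Figure D2:**
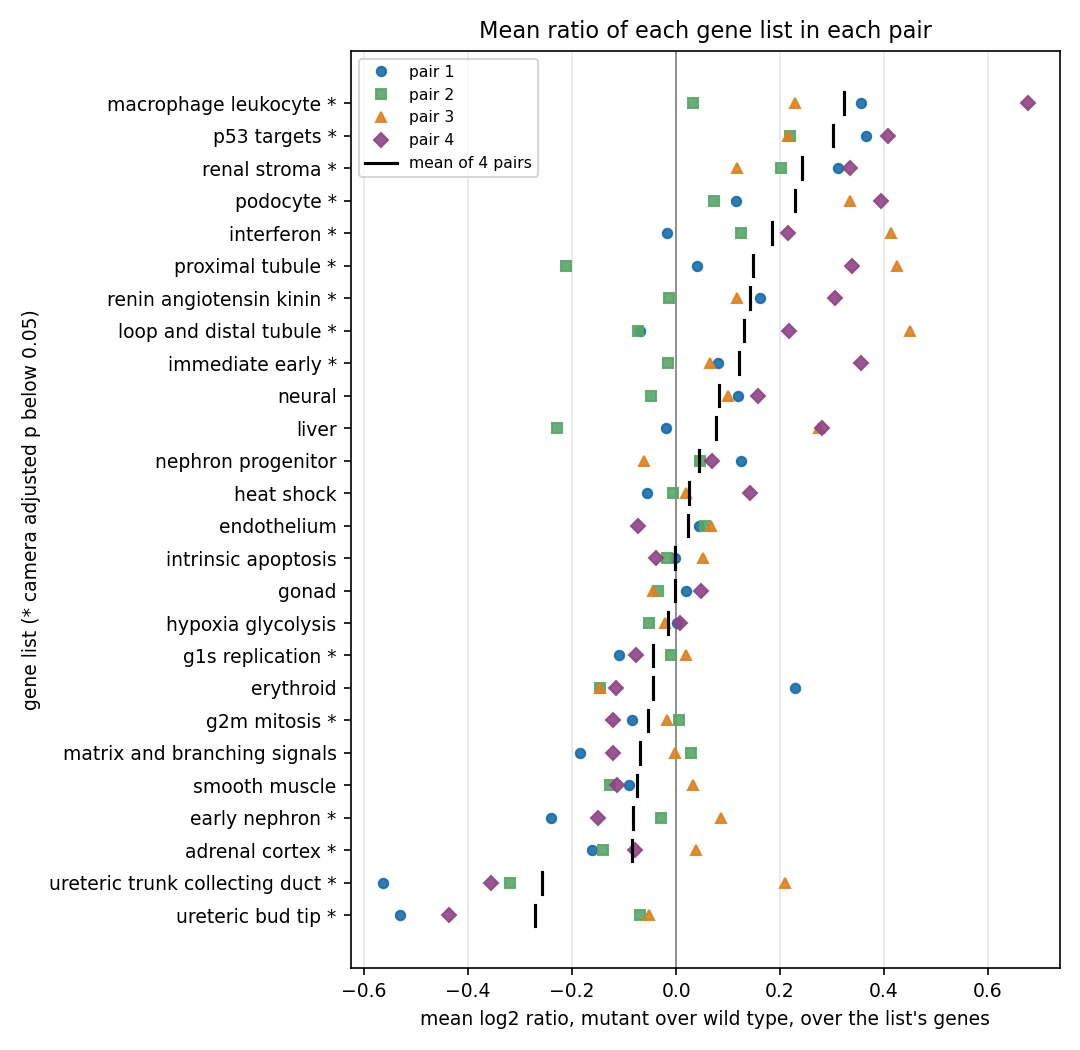
Mean log2 ratio of mutant over wild type (horizontal axis) of the measured genes of each of the 26 lists (vertical axis), with 1 symbol per pair and a bar at the mean of the 4 pairs. Means run from 0.32 for macrophages and leukocytes to -0.27 for the ureteric bud tip, and asterisks mark the 15 lists with a camera adjusted p below 0.05.

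Another 8 lists were called by camera with smaller means, and none of these calls held with an estimated correlation, where their adjusted p lay between 0.553 and 0.698. The proximal tubule list was at 0.15 (22 of 27 genes higher), with the endocytic receptor gene Lrp2 at 0.36 ± 0.11 and the transcription factor gene Maf at 0.35 ± 0.11. The list of the loop of Henle and distal tubule was at 0.13 (16 of 20 higher), with the prostaglandin receptor gene Ptger3 at 0.41 ± 0.12. Without pair 3 these lists were at 0.06 and 0.03, and neither was called then or without pair 4. Without pair 2 they were at 0.27 and 0.20, and without pair 1 the latter was at 0.20. Renin-angiotensin and kinin genes were at 0.14 (11 of 13 higher), with the peptidase gene Mme at 0.45 ± 0.14 and the angiotensin receptor gene Agtr1b, well above background in 6 of 8 wild-type channels, at 0.25 ± 0.08, and this list was at 0.09 without pair 4. Immediate early genes were at 0.12 (14 of 18 higher), and at 0.04 without pair 4. Adrenal cortex genes were at -0.09 (7 of 8 lower), with the steroidogenic enzyme gene Cyp17a1 at -0.55 ± 0.15. None of these 3 lists was called without pair 1 or without pair 4.

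Early nephron genes were at -0.08 (14 of 19 lower), S phase genes at -0.04 (24 of 30 lower) and mitosis genes at -0.05 (25 of 33 lower), but with median centring these means were 0.07, 0.12 and 0.11, below the median of all genes of 0.14, and none was called. In the early nephron list Wnt4, a signal that starts nephron formation, was at -0.34 ± 0.08, Lhx1, shared with the tip list, at -0.26 ± 0.08, Cxcr4 at -0.25 ± 0.06 and Sfrp2 at 0.21 ± 0.05. Without pair 1 this list was at -0.03 and without pair 3 at -0.14. In the S phase list Uhrf1, needed to maintain DNA methylation, was at -0.21 ± 0.06, and without pair 1 the list was at -0.02 and on Cy3-mutant arrays alone at 0.0058. Neither the early nephron nor the S phase list was called without pair 1 or without pair 4. In the mitosis list, which was at -0.03 without pair 4, the cyclin gene Ccnb1 was at -0.18 ± 0.06 and Cdca8 at -0.15 ± 0.05, but Cdca8 was at 0.02 with median centring.

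The other 11 lists were not called, with camera adjusted p from 0.0680 to 0.842. The nephron progenitor list was at 0.04 (10 of 19 genes higher), at 0.02 without pair 1, at 0.08 without pair 3 and at 0.0096 with the sex difference as a covariate. Its genes went both ways, and fry's test of changes in either direction, which does not compare the list with other genes, called it (adjusted p = 0.0145). With p adjusted over the list alone, 1 gene rose, against 0 over all genes. The integrin gene Itga8 was at 0.29 ± 0.09 and Gdnf, the growth factor that attracts the ureteric bud, at -0.24 ± 0.09. Endothelium was at 0.02 (0.06 without pair 4 and 0.0087 without pair 3), red blood cells at -0.04, smooth muscle at -0.07, neurons at 0.08, liver at 0.08, and hypoxia and glycolysis at -0.02. Signalling and matrix genes of branching were at -0.07. The means with 1 pair left out ran from -0.10 to -0.03 for branching and -0.14 to -0.01 for red blood cells. They ran from 0.06 to 0.13 for neurons and -0.02 to -0.0036 for hypoxia and glycolysis. With 1 pair left out camera called 4 of the 11 lists, red blood cells at -0.14 without pair 1, liver at 0.18 and branching at -0.10 without pair 2, and smooth muscle at -0.11 without pair 3. The liver list was at 0.011 without pair 3 and 0.0090 without pair 4. Gonad genes were at -0.0028. Intrinsic apoptosis genes outside the p53 list had a mean of -0.0014, a median of 0.01 and a camera test in the upward direction. Heat shock genes had a mean of 0.03, a median of -0.02 and a camera test in the upward direction. With median centring, red blood cell, smooth muscle, gonad, apoptosis, hypoxia and branching lists had means between 0.03 and 0.14, where the median of all genes was 0.14.

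Sex-linked transcripts differed within the pairs. The Y-linked genes Eif2s3y, Kdm5d and Ddx3y were at 3.91, 2.99 and 2.41 in pair 1, at 2.26, 1.38 and 0.94 in pair 2, at -2.02, -1.88 and -1.27 in pair 3 and at 4.09, 2.97 and 2.23 in pair 4. They were well above background in 3, 3 and 2 of the 8 wild-type channels and in all 8 mutant channels, those of pair 3 included. Xist, the transcript of the inactive X chromosome, which was chosen after its values were seen, was at -2.71, -0.23, 2.48 and -2.80 in pairs 1 to 4. The mutant RNA therefore held more Y-linked transcript than its wild-type partner in pairs 1, 2 and 4 and less in pair 3. Xist was well above background in 7 of 8 mutant and 7 of 8 wild-type channels. Most mutant RNAs thus held both Xist and Y-linked transcripts above background, so these values do not assign 1 sex to each RNA.

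**Figure D3:**
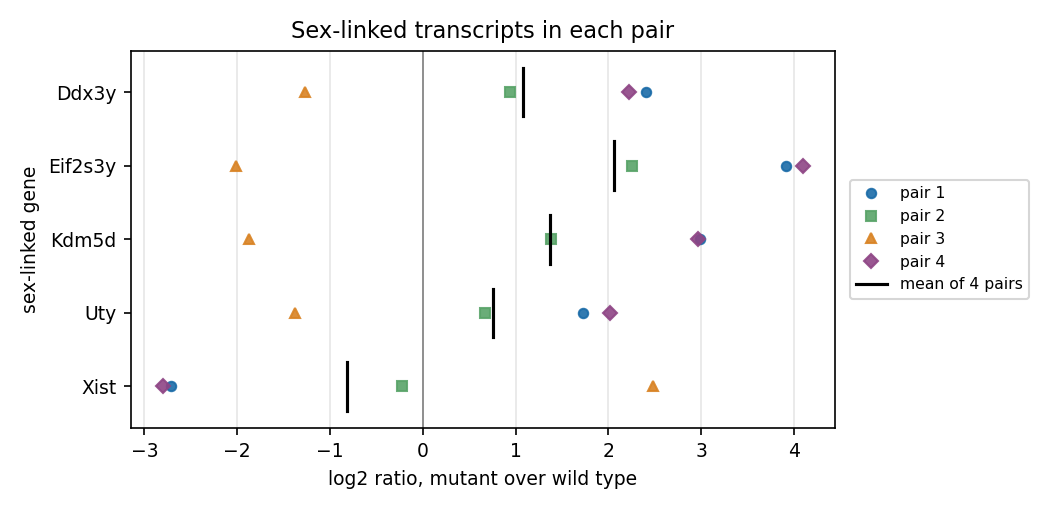
Log2 ratio of mutant over wild type (horizontal axis) of 5 sex-linked transcripts (vertical axis), with 1 symbol per pair and a bar at the mean of the 4 pairs. The 4 Y-linked genes lie above 0 in pairs 1, 2 and 4 and below 0 in pair 3, and Xist lies on the opposite side in each pair.

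Pair 4 held genes with large ratios that the other pairs did not show. Over 8-fold apart in pair 4 and under 2-fold in each other pair were 17 genes higher and 5 lower, and the same limits gave 0 genes in each of pairs 1, 2 and 3. Among them, all chosen after their values were seen, were the chemokine genes Ccl20 at 5.53 and Cxcl1 at 4.51, Spp1, which encodes osteopontin, at 5.38, the complement gene C3 at 4.26, the keratin gene Krt6b at 3.78 and the acute-phase gene Saa3 at 3.58. The neutrophil genes S100a8 and S100a9, members of the macrophage and leukocyte list and chosen after their values were seen, were at 3.04 and 3.88 in pair 4. Over the 17 genes, the mutant RNA of pair 4 lay above the other mutant RNAs by a median of 4.88, and the wild-type RNA of pair 4 above the other wild-type RNAs by 0.91. No p53 target of the fixed list was among the 22 genes.

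**Figure D4:**
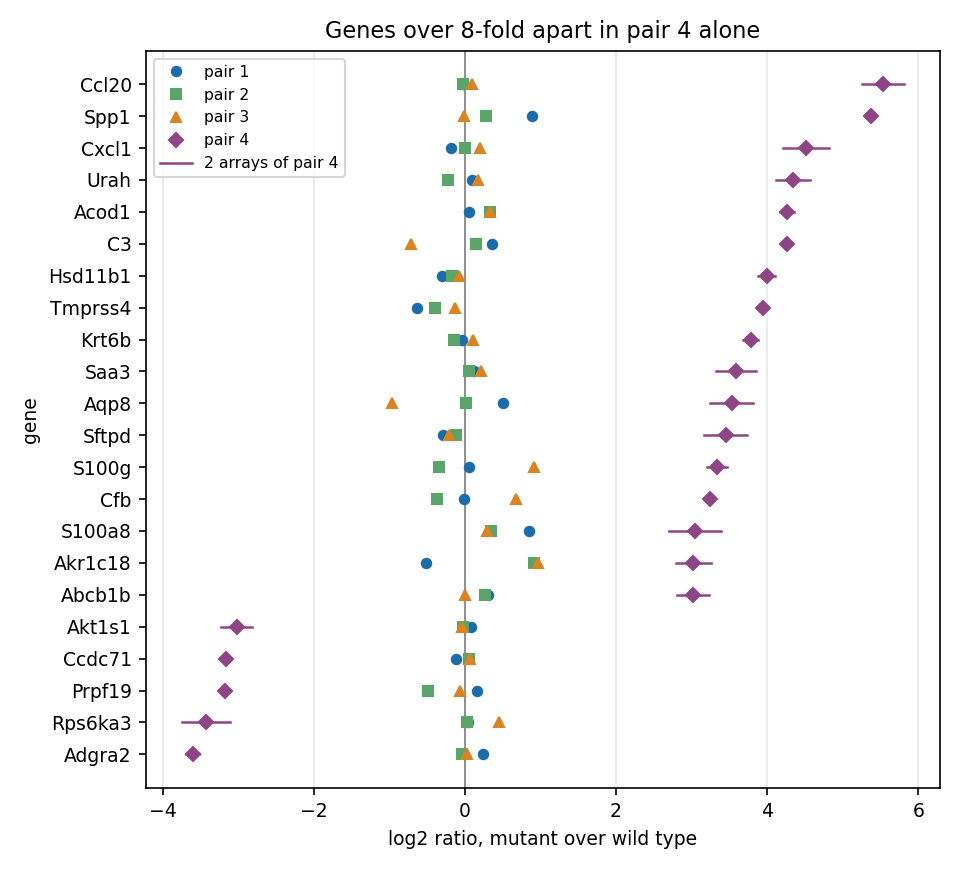
Log2 ratio of mutant over wild type (horizontal axis) of the 22 genes over 8-fold apart in pair 4 and under 2-fold apart in the other pairs (vertical axis), with 1 symbol per pair and a line between the 2 arrays of pair 4. Both arrays of pair 4 lie far from 0 for each gene, with medians of 3.69 and 3.88 over the 17 higher genes.

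Across genes, which are not independent replicates, the 2 dye orientations of a pair correlated with Pearson's r of 0.54, 0.23, 0.34 and 0.60 in pairs 1 to 4 and Spearman's rho of 0.33, 0.06, 0.15 and 0.39. Between pairs, Pearson's r across genes was 0.34 for pairs 1 and 2, 0.31 for pairs 2 and 4, 0.20 for pairs 1 and 4, 0.14 for pairs 3 and 4, -0.03 for pairs 2 and 3 and -0.23 for pairs 1 and 3. The dye orientations differed past a limma adjusted p of 0.05 for 5045 genes, and for 1225 genes all 4 arrays of 1 orientation had the opposite sign to all 4 of the other.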

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

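The tests of sex, dye, cell composition, array artefact, macrophages and single probes in this part were chosen only after the results were seen, while the counts over other splits of the samples were planned.

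Transcripts of the p53 target list were higher in the mutant by a mean of 0.30, in 4 of 4 pairs. A difference in the sex of the embryos is argued against as its cause, because the list mean was 0.22 in pair 3, where the sex-linked transcripts differed the other way, and above 0 on both arrays of that pair (0.18 and 0.25). Dye bias is argued against by the lowest list mean over the 8 arrays, which was 0.18. The 8 ways to turn the 4 pairs are too few for a share under 0.05: 1 of the 8, the real one, gave the largest value of -log10 p (11.0), and the highest other, with pair 3 turned, gave 6.33. Higher p53 activity in cells that lost Mdm4 may account for the list as a hypothesis, found and tested on the same data. The call stays open, because it did not hold in camera with an estimated correlation (unadjusted p = 0.0553, adjusted p = 0.553). The tip list had the same adjusted p in that test with an unadjusted p of 0.149, so these adjusted values do not rank the lists.

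The ureteric tip and trunk lists were lower and the renal stroma list was higher in the mutant. For the trunk and tip lists the genotype and the sex of the embryos cannot be told apart, because lines through the 4 pairs gave -0.11 and -0.17 at no sex difference, with 95% intervals from -0.45 to 0.22 and from -0.54 to 0.20. A difference in sex as the whole cause is argued against for the stroma list, where such a line gave 0.20 (0.14 to 0.25), though its mean was lowest in pair 3 (0.12). A smaller share of ureteric epithelium in the mutant kidneys could lower both ureteric lists in every pair, which the trunk list, at 0.21 in pair 3, did not show, and it cannot be told apart from lower expression per cell, since the tip minus trunk difference was -0.015 with a 95% interval from -0.36 to 0.33 over only 4 pairs. Such a smaller share would raise all other cell types alike, and for the stroma list this is argued against by a stroma minus nephron progenitor difference of 0.20 (95% interval 0.12 to 0.27), whereas stroma minus endothelium was 0.22 (-0.03 to 0.47). A change in the stroma itself stays open as a hypothesis.

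Genes over 8-fold apart in pair 4 alone were 17 higher and 5 lower. An artefact of an array or a dye is argued against for the higher genes, because the lower of the medians of the 2 arrays was 3.69. More macrophages in that mutant RNA are argued against as the source of changes over 8-fold by a median of 0.37 over the macrophage and leukocyte list in pair 4, with its 2 brightest genes Csf1r at 0.35 and Pf4 at 0.29. A smaller rise in macrophages stays open, with Cx3cr1 at 0.76, Adgre1 at 0.86, Mrc1 at 0.55 and Cd14 at 1.71. Other genes of the list, Cd68 at -0.13, Lyz2 at -0.10, Coro1a at -0.08 and Laptm5 at -0.01, did not rise. The list mean of 0.68 includes S100a8 and S100a9, its highest values. S100a8 and S100a9 at 3.04 and 3.88 leave neutrophils possible, and no separate list for them was tested. Poor binding of single probes to that RNA could explain the 36 probes over 4-fold lower in pair 4 alone, and it cannot be told apart from lower transcript. The 22 kept probes of their genes other than each gene's lowest had a median of -0.21, with 8 below -1 and 14 above -0.5. Among these 22, probes of Akt1s1, Prmt1 and Cd82, at -2.80, -2.62 and -2.24, belong to the 36 as well and were below -2 by selection. A difference between these embryos other than genotype was not tested.

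Counts of calls over other splits bear on the remaining results. The 8 ways to turn the pairs are too few for a share under 0.05. For genes past the threshold the real count was 0 and the highest other 0, so that 8 of 8 gave as many. For lists called the real count was 15 and the highest other 17, with pair 2 turned, so that 2 of 8 gave as many.

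In 12 of 113 genes and lists checked, 1 pair stood far from the other 3, where chance gives about 5.65 (1 in 20 such groups). However, 6 of the 12 are genes chosen because pair 4 stood apart, and many other genes were chosen by a small p over the same pairs. The 12 therefore cannot be set against that number, and whether they exceed chance stays open. In pair 1 these were Zfp365 at 0.92, Sptan1 at -0.15 and the red blood cell list at 0.23. In pair 3 they were Plcxd3 at 0.46 and Ccnb1 at -0.28. In pair 4 they were the endothelium list at -0.074, S100a9 at 3.88, Ccl20 at 5.53, Spp1 at 5.38, Cxcl1 at 4.51, Saa3 at 3.58 and Krt6b at 3.78, of which the last 6 are the genes so chosen.

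The dye orientations differed past a limma adjusted p of 0.05 for 29 of the 87 genes checked, against 5045 of all 16013 genes, and orientation went together with the position on the slide. The values here are the mean ratio with mutant RNA in Cy5 minus that with mutant RNA in Cy3, divided by 2. Above 0 were Lum at 0.35, Eif2s3y at 0.23, Mdm4 at 0.18, Hap1 at 0.15, Gdnf at 0.13, Pdyn and Lrp2 at 0.11 each, and Aif1 at 0.11. Below 0 the largest were Trp53 at -0.84, Cyp17a1 at -0.33, Bax at -0.30, Wnt11 and Krt8 at -0.26 each, Rtp4 at -0.22, and Sp6 and Pqlc3 at -0.20 each. Lhx1, Wnt9b and Dkk2 were at -0.18 each, Col3a1 and Saa3 at -0.17 each, S100a9 and Ccl20 at -0.15 each, and Mfsd13a at -0.14. Krt23 and Uhrf1 were at -0.13 each, Gcdh and Sfrp2 at -0.12 each, and Krt18 at -0.10.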

How the results depend on the processing

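The centring on the tested genes and the sex covariate were chosen only after the results were seen, and the other settings were planned. Of 1816 values of the 87 genes named, 1758 kept their direction and their side of the threshold, 48 passed it and 10, of 8 genes, changed sign. Over 22 settings tested with camera at the preset correlation of 0.01, the p53, tip, trunk, stroma, macrophage and interferon lists were called in all 22. Their means ran, in that order, from 0.24 to 0.44, -0.35 to -0.13, -0.41 to -0.11, 0.18 to 0.40, 0.21 to 0.53 and 0.11 to 0.36. With an estimated correlation camera called 0 lists. The 22 settings are not independent, and separate channels with the replicate block repeat the main fit by construction. The podocyte list was called in 21, and the other 8 called lists in fewer. With all pairs, the branching list was called with the median of a gene's probes (-0.10) and over probes (-0.09), and smooth muscle on Cy3-mutant arrays (-0.18) and, below the median of all genes, with median centring. Where a cause is not named below, the cause was not tested. Signal over background limits the dim genes: Ddx3y, Eif2s3y, Kdm5d and Ccl3 were well above background in only 2 to 4 of the 8 wild-type channels.

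The count of genes called, 0 in the report, was 42 with median centring (12 in the p53 list), 39 with all 8 arrays, a dye coefficient and the pair as a random block (11 in the p53 list), 1 with the sex covariate and 1 at an adjusted p of 0.10. The 42 and the 39 shared 27 genes. With each pair left out it was 0, as in the other settings except the unpaired fit below. The count of lists called, 15 in the report, was 9 with median centring, 7 on Cy3-mutant arrays, 8 with centring on the tested genes, 0 with an estimated correlation, 0 with fry in 1 direction, and 8 to 17 with 1 pair left out, the 8 without pair 4. Fry's test of changes in either direction called 3 lists, p53 targets, renal stroma and nephron progenitors. The estimated correlation and fry leave the list means as they are by construction. The adjusted p of camera with an estimated correlation and of fry were 0.553 and 0.153 for the p53 list (0.30), 0.553 and 0.399 for the tip list (-0.27), and 0.564 and 0.422 for the trunk list (-0.26).

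Pairing was left out by splitting the channels and comparing the 4 wild-type with the 4 mutant RNAs. Without the replicate block limma then called 6 genes, all higher (Ccng1, Eda2r, Plcd4, Sp6, Rbm45 and 1700007K13Rik), and 11 lists. With the block it called 0 genes and 15 lists, as the ratios do by construction. Compared within 1 dye on different arrays, the RNAs of a pair correlated at -0.07 to 0.53. The 8 comparisons were the 4 pairs in each dye, and in 5 of them the wild-type RNA correlated best with its own partner. These were pairs 1 and 4 in both dyes and pair 2 in Cy3, with pair 3 in neither. In that unpaired fit chance can be excluded for the 6 genes only if the 8 RNAs are taken as exchangeable, which leaves out their pairing: 1 of the 35 splits, the real one, gave as many, and the highest other gave 2. At an unadjusted p under 0.05 the real split gave 1004 genes and 8 others gave more. The split of pairs 1 and 2 against pairs 3 and 4 gave 3045, and the other splits between whole pairs gave 671 and 783.

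Signs changed as follows. With median centring, which moved the median of all genes to 0.14, the early nephron list was at 0.073, red blood cells 0.079, smooth muscle 0.031, gonad 0.089, S phase 0.12, mitosis 0.11, apoptosis 0.14, hypoxia 0.14, branching 0.062 and Cdca8 0.020. The gonad list was at 0.011 with the smaller offset, 0.019 without background correction, 0.059 with processed signals, 0.059 with the deposited table and 0.032 on Cy5-mutant arrays. The apoptosis list was at 0.0017 without background correction, 0.0096 with processed signals, 0.0096 with the deposited table, 0.017 on Cy5-mutant arrays, 0.0012 with centring on the tested genes and 0.014 with the sex covariate. Mdm2 was at -0.041 with the median of its probes, and heat shock at -0.0088 over probes. On Cy5-mutant arrays endothelium was at -0.069 and smooth muscle at 0.035. On Cy3-mutant arrays red blood cells were at 0.011, S phase 0.0058, hypoxia 0.016, Trp53 0.62, Mdm2 -0.079 and Bax 0.10. With centring on the tested genes liver was at -0.019, and with the sex covariate Xist was at 0.35. With 1 pair left out, values ran from -0.020 to 0.011 for gonad, -0.019 to 0.011 for apoptosis, -0.014 to 0.052 for heat shock, -0.026 to 0.062 for Mdm2, -0.78 to 0.033 for Ret, -0.069 to 1.59 for C3 and -0.024 to 1.28 for Krt6b. Leaving out pair 4 removes the value that sets the means of C3 and Krt6b, and leaving out pair 1 the lowest value of Ret.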

Other observations

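The test of the genes around Mdm4 was planned before its result was seen, and the genes and probes singled out in this part were chosen only after their values were seen, 1700007K13Rik among them because the naming rule left out such symbols.

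Some transcripts outside the p53 list were also higher in the mutant in all 4 pairs. The transcript 1700007K13Rik was higher by 1.27 ± 0.12 (1.51, 1.04, 0.96 and 1.57 in pairs 1 to 4) and Tescl by 1.32 ± 0.20 (1.24, 0.87, 1.03 and 2.14), each on 8 of 8 arrays. Matn2, which encodes the matrix protein matrilin 2, was higher by 0.70 ± 0.13 (0.93, 0.57, 0.27 and 1.03). None of them passed over all genes with limma on the 4 pairs. Each was called with median centring (1.35, 1.38 and 0.86) and with all 8 arrays in 1 fit, a dye coefficient and the pair as a random block.

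Single probes also stood apart in pair 4. Over 4-fold apart in that pair, and within 0.70 on the log2 scale in the others, were 26 probes higher and 36 lower, against 0 in pairs 1 and 2 and 1 lower probe in pair 3. The 36 lower probes had a median of -2.44 and stood at a median brightness percentile of 74.6, and 31 of them were named, for 28 genes. Akt1s1 was at -3.02, Ccdc71 at -3.16, Prpf19 at -3.17, Rps6ka3 at -3.43 and Adgra2 at -3.60 on their brightest probe, and another probe of Akt1s1 was at -2.80, but the other kept probes of Rps6ka3 were at -0.06 and -0.06.

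Alleles of the targeted strain that travelled with the Mdm4 locus could change the expression of its neighbours. The 40 tested genes nearest Mdm4 had a median absolute t of 1.04, against 0.981 over 9496 runs of 40 neighbouring genes, which put it at the 59.4th percentile. This shows no shift of these genes as a set. A median over 40 genes cannot show a passenger effect on a few of them, so that stays open.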
